A study of Drosophila melanogaster with 4 samples.

How the data were processed

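Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been done with an antibody against GFP on whole *Drosophila melanogaster* embryos aged 6 to 24 h that carried Chinmo, a BTB zinc finger transcription factor, as a fusion with enhanced GFP. Per the labels, the 4 libraries are biological replicates 1 to 4 of 1 group, chromatin was fragmented by sonication, and control libraries exist under a separate label; those controls were not analysed here. The antibody field of the labels names Chinmo while the description names GFP; the description was followed, and if the antibody was against Chinmo itself the signal would not come from the tagged protein alone. The age field of the labels holds a number of hours that cannot be an embryo age, so the age was taken from the sample source label.

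The peak positions are on assembly dm6, per the labels. For each library the authors deposited a list of peaks passed by an irreproducible discovery rate (IDR) analysis and a longer list of ranked peaks; which parts of a library the IDR analysis compared, the aligner and the peak caller are not given in the sources used here. Each peak carries a deposited signal value, which is the peak's own value from the authors' peak calling and has no unit stated. It also carries a deposited score, and the lowest score was 830 in all 4 thresholded lists, which is an IDR of 0.0100 under the usual scaling of that score. Between 4.33% and 5.32% of the ranked peaks at or above that score were not in the thresholded list of the same library. Whether a further step removed them is not described in the sources used here, and the reason was not examined. The series also holds 7 thresholded lists described as derived from the alignments of all 4 libraries, though which libraries each compares is not stated. Among them were 1 named as conservative with 5841 peaks and a longest one with 13848 peaks. Both were used as alternatives, and either may rest on fewer than 4 libraries. A further 7 ranked lists of the whole series, for which the libraries compared are not stated either, were not used here. Read depth was unknown, because the lists hold no read counts. A peak list gives no value for a region that was not called, so a missing peak is not a measured absence of binding.

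Peaks on the arms 2L, 2R, 3L, 3R, 4 and X were used, which left out 3 peaks of replicate 3. A peak's position was its summit. Signal values served only to rank the peaks within 1 list, as the percentage of the list's peaks with a signal value no higher (100 for the strongest peak). The summits of the 4 thresholded lists were joined where windows of 100 bp to each side overlapped, and a cluster with summits from at least 3 of the 4 libraries was called a shared region, with the median summit as its centre. Gene models came from Ensembl annotation BDGP6.54 (release 115) and sequence from the RefSeq genome of Release 6, the assembly that dm6 names; coordinates are 1-based. A gene was called bound when a shared region's centre lay within 1000 bp of any of its annotated transcription start sites (TSS), and 13945 protein-coding genes entered these tests. Each centre or summit was placed in 1 of 6 classes, in the order promoter (within 1000 bp of a protein-coding TSS), 5' UTR, CDS exon, 3' UTR, intron and intergenic.

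The groups of genes were 23 lists of pathways, cell types and gene families. They, the 20 sequence motifs, the main tests and most alternatives were fixed before the data were examined; the later ones are named where they are reported. Of the list names, 13 were matched through an older symbol and 8 matched no protein-coding gene of the annotation. The genes named in the text are the nearest genes of the 15 shared regions found in all 4 libraries with the highest mean rank percentile; chinmo, br, mamo, Imp, Syp, Eip93F and the let-7 complex whatever their values; for each list past the threshold, up to 4 members with the highest-ranked region and up to 2 members, first in alphabetical order, with no region; and for each other list up to 2 members with the highest-ranked region. Genes named outside that rule are marked as such.

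Overlap between replicates was tested against 1000 circular shifts of a list along each arm (permutation test, one-sided), and positions relative to genes against 1000 circular shifts of the shared regions (permutation test, two-sided). Gene lists and classes of non-coding genes were tested with Fisher's exact test, the X chromosome with an exact binomial test, and motifs with McNemar's exact test, which compared the window of 50 bp to each side of the centre of a region with a window of the same width centred 500 bp to 1 side, the side being drawn at random. Every 6-mer, joined with its reverse complement, was tested in the same way (2080 in all). Adjusted p-values are Benjamini-Hochberg values within each family, and the threshold was 0.05. Log2 odds ratios were computed with 0.5 added to each cell. Shares of genes and regions carry exact (Clopper-Pearson) 95% intervals where given; they cover counting error only. Because the replicates form 1 group, no comparison between conditions was possible, and tests over genes or regions describe these 4 libraries, not a wider set of embryos.

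The steps were tested on simulated data. In each simulated list 1000 planted sites were kept with a probability of 0.95, and 1500 random peaks were added. Of the sites, 98.3% were recovered within 40 bp, and 0 shared regions lay away from planted sites. The share recovered is set by that probability, so it checks the steps alone. How many real sites the 4 lists recover cannot be read from it. A planted gene list reached a log2 odds ratio of 3.81 while 0 of the 22 other lists passed the threshold, and a motif planted in 30% of 2000 sequences was found in 29.9% of them. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The alternatives tried were other definitions of a shared region, stricter lists, the lists of the whole series, regions in at least 2 of the 4 libraries, each replicate left out (with regions in 2 of the other 3 kept, so that the rule is looser as well), other windows and flanks, other expectations, and random genes matched on gene length and number of TSS.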

Results

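Binding of Chinmo-eGFP was mapped in 4 biological replicates of whole embryos aged 6 to 24 h with an antibody against GFP. Chinmo is a BTB zinc finger transcription factor known for its role in the timing of neuronal identity and in stem cells of the testis. The labels give 1 group and no second condition, so the comparisons concern how well the replicates match and where the bound regions lie. The thresholded lists held 3435, 4415, 2225 and 3038 peaks for replicates 1 to 4, a mean of 3278 ± 910 (SD, n = 4). The ranked lists were longer, at 39725, 27034, 30166 and 34150 peaks. Median peak widths were 400, 430, 396 and 420 bp. Read depth was unknown.

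The replicates shared their strong regions and differed in the weak ones. Of the 500 strongest summits of a library, between 81.8% and 97.0% lay within 100 bp of a summit in another library's list, over the 12 ordered pairs of libraries. For whole lists the share ranged from 35.2% (95% interval 33.8% to 36.7%; summits of replicate 2 found in replicate 3) to 70.05% (68.4% to 71.7%; replicate 4 found in replicate 2), with a mean of 56.4%. List length limits these shares, as a long list cannot be matched fully by a short one. The lowest share stands for 1555 of 4415 summits of replicate 2, while in the other direction 1555 of 2222 summits of replicate 3 (69.98%) were matched. Circular shifts gave a mean of 0.499%, and every pair reached an adjusted p of 0.001 by the one-sided permutation test, the smallest that 1000 shifts can give. The summits formed 5775 clusters, of which 2284 came from 1 library, 1341 from 2, 983 from 3 and 1167 from all 4. The 2150 clusters with at least 3 libraries are the shared regions described from here on; after shifting, the mean was 1.76 and the highest count 9 (one-sided permutation p = 0.001, the smallest possible). Replicate 3, with the shortest list, lacked 537 of the shared regions in its thresholded list, but 82.3% of those had a summit within 100 bp in its ranked list, against 4.49% after shifting. For replicates 1, 2 and 4 that share was 87.8%, 85.9% and 86.9%.

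**Figure D1:**
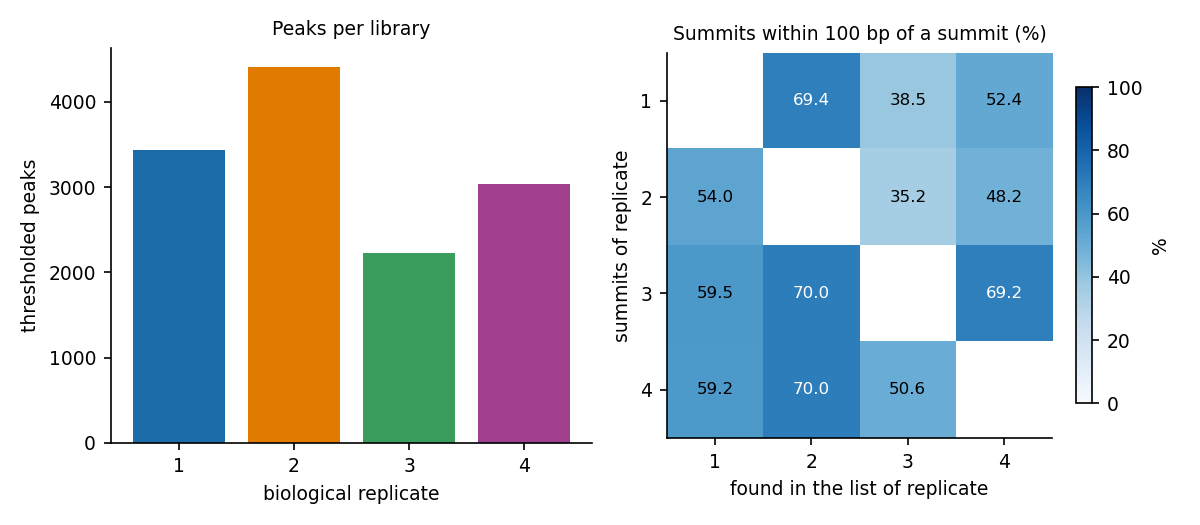
Left, the number of thresholded peaks (y axis) in each of the 4 biological replicates (x axis). Right, the percentage of the summits of the library in each row that lay within 100 bp of a summit of the library in each column; values run from 35.2% to 70.05%, and the columns of replicate 2, the longest list, hold the highest shares for replicates 1, 3 and 4.

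The peaks with the highest signal values lay at the chinmo gene itself. Of the 15 shared regions with the highest mean rank, 8 lay around chinmo (FBgn0086758; arm 2L, 1651258 to 1704682, plus strand), and the first 5 places were all held by that locus. The region at 1632726 to 1633273, an intergenic site 18197 bp upstream of the nearest chinmo TSS, ranked 1, 1, 3 and 1 in replicates 1 to 4. An intergenic region at 1643457 to 1643993, 7479 bp upstream, ranked 2 in all 4 libraries. A region in an intron of chinmo (1656765 to 1657518) ranked 3, 3, 6 and 3. The chinmo promoter was bound as well, by a region at 1651109 to 1651419 centred 16 bp from a TSS, with a mean rank percentile of 99.0 ± 0.701 (SD, n = 4). In all, 28 shared regions lay between 1618892 and 1737461 on 2L. The 130 kb around them held 39, 38, 32 and 31 thresholded peaks in replicates 1 to 4, where the median of 1025 other windows of 130 kb was 2, 3, 1 and 2 and the highest was 30, 27, 18 and 20. In the ranked lists the excess was smaller, with 137, 119, 107 and 129 peaks there against medians of 39, 26, 30 and 33 and highest counts elsewhere of 110, 86, 83 and 97. The window was set after the values were seen, and the number of copies of the locus in the transgenic flies is not known. Not all regions of the locus ranked high. Some upstream of chinmo and in the gene had mean rank percentiles as low as 34.6 and 19.3, and the promoters of cpb, mRpL48, Eno and CG17646 beyond its 3' end had mean rank percentiles of 74.6, 64.0, 65.4 and 39.9; these 4 neighbours were named after their values were seen.

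**Figure D2:**
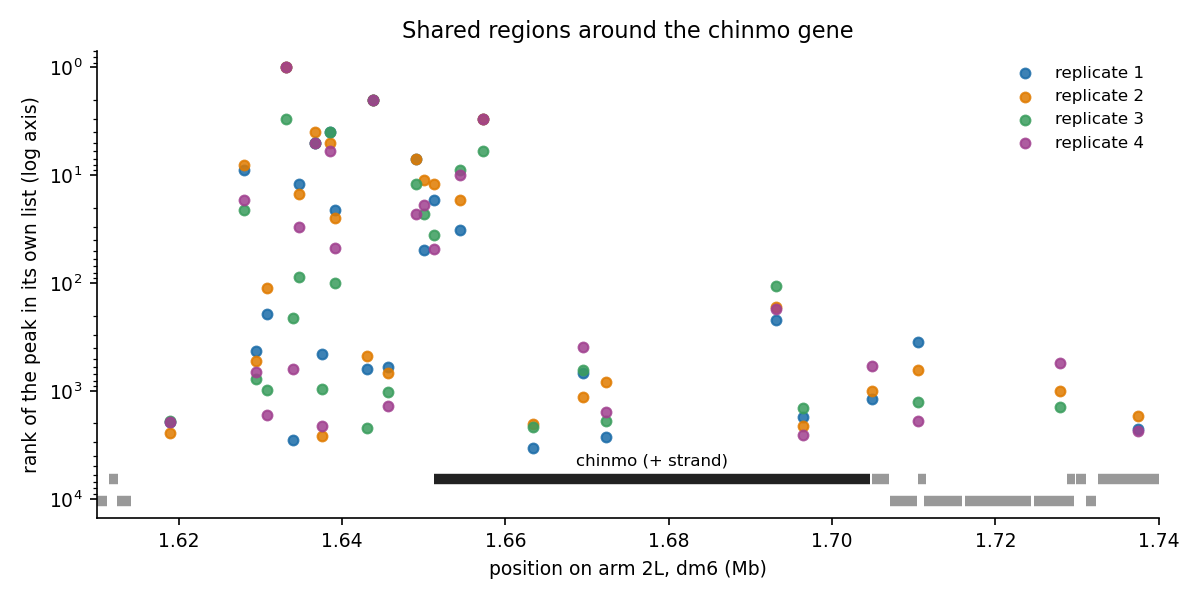
Shared regions around chinmo on arm 2L (x axis, position in Mb on dm6) against the rank of their strongest peak in each library's own list (y axis, log scale, rank 1 at the top), coloured by replicate. Bars near the bottom are protein-coding genes, with chinmo in black, the upper row on the plus strand and the lower on the minus strand; ranks 1 to 7 in replicates 1 and 2 fall mostly upstream of chinmo and in its intron.

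The other strongest regions lay at 7 genes. A region in an intron of KCNQ, a gene named after its values were seen, 1120 bp upstream of a TSS of mlt (arm 2R, 10159783 to 10160322), ranked 6, 6, 15 and 7. The promoter of Sox14, which encodes a Sox-family transcription factor, was bound 279 bp upstream of its TSS (2R, 23978281 to 23978886) and ranked 20, 43, 1 and 8. The remaining ones were in the 3' UTR of Ppa (2R, 22686018 to 22686388), at the promoter of Capr (3L, 18673078 to 18673338), in an intron of ftz-f1, which encodes a nuclear receptor (3L, 18759192 to 18759509), and in intergenic sequence near NimC3 (2L, 14021710 to 14022037) and CG15629 (2L, 4811438 to 4812061). Their mean rank percentiles ran from 99.3 to 99.5. An intergenic site nearest to RFeSP ranked 9, 8, 21 and 17, and belongs to the chinmo cluster (2L, 1627883 to 1628183). Only 2 of the 15 strongest regions were promoter-proximal.

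Genes that act with Chinmo in developmental timing were bound unevenly. Imp, an RNA-binding protein gene, had a promoter region 152 bp from a TSS with a mean rank percentile of 71.7 ± 9.20 (SD, n = 4; X, centre 10815787). The gene mamo, another BTB zinc finger factor, had 1 intronic region at 97.4 ± 1.13 (SD, n = 4; X, centre 13890583), 42760 bp from its nearest TSS. The gene br (broad, a BTB zinc finger gene of the ecdysone response) held 1 region within its borders, which lay 972 bp from a TSS of Mur2B, also named after its values were seen, and ranked low, at 19.9 ± 11.9 (SD, n = 3). No shared region lay within Syp, Eip93F or the let-7 complex or within 1000 bp of their TSS. Replicate 3 had 1 peak in Syp, and 0 peaks were listed in Eip93F and the let-7 complex in any library.

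Bound regions lay mostly at promoters. Of the 2150 shared regions, 1497 (69.6%, 95% interval 67.6% to 71.6%) lay within 1000 bp of a protein-coding TSS, against 20.4% after circular shifts and at most 24.5% in any shift (two-sided permutation, adjusted p = 0.0024). The share in the 4 library lists was 67.2% ± 3.77 (SD, n = 4). The median distance of a shared region to the nearest TSS was 147 bp, and 67.3% of the promoter-proximal regions were upstream of it. A total of 440 of them lay within 1000 bp of TSS of more than 1 gene. Introns held 448 regions (20.8%, against 36.1% after shifting) and intergenic sequence 175 (8.14%, against 28.5%). Coding exons held 6 regions and 3' UTRs 16, against shifted shares of 10.7% and 3.79%; all 4 classes were below the shifts with an adjusted p of 0.0024 in the permutation test. The 5' UTR class outside promoters held 8 regions, 0.372% against 0.457% after shifting, and did not pass the threshold (permutation, adjusted p = 0.701).

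**Figure D3:**
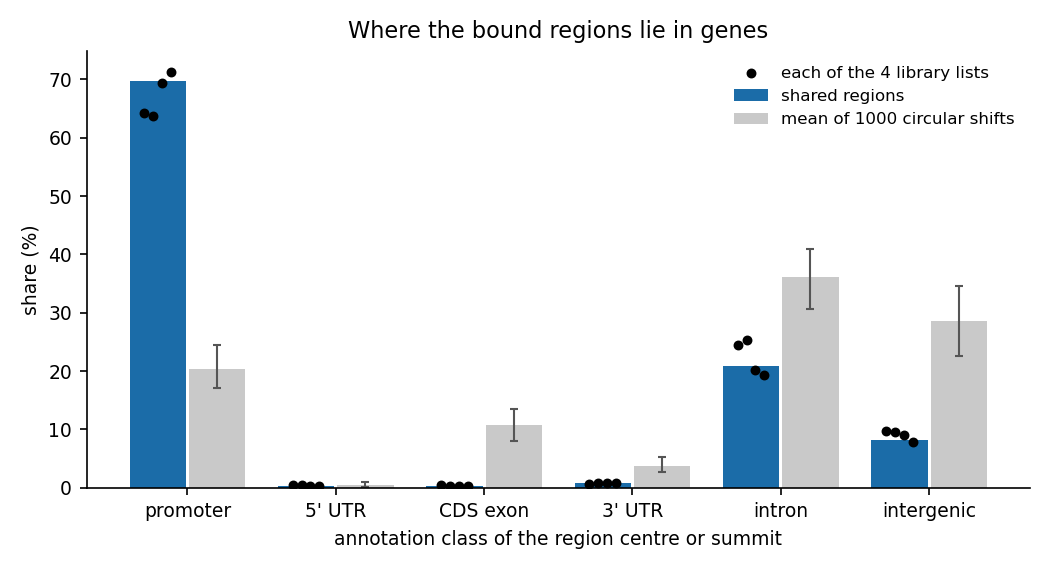
Share of shared regions in each annotation class (blue bars, y axis in %), with the 4 library lists as black points and the mean of 1000 circular shifts as grey bars; whiskers on the grey bars run from the lowest to the highest shift. Promoters hold 69.6% of the shared regions and 20.4% of the shifted ones.

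The X chromosome held fewer regions than its TSS would give. It carried 323 of the 2144 shared regions on X and the autosomal arms 2L, 2R, 3L and 3R, 15.1% (95% interval 13.6% to 16.7%) against 17.1% expected from TSS counts (log2 ratio -0.19, two-sided exact binomial test, adjusted p = 0.0129), and it was below the expectation in 4 of 4 libraries. In the library lists the share on X was 14.7% ± 1.31 (SD, n = 4); it was lowest in replicate 2 at 13.5%, and in replicate 3, at 16.4%, it did not pass the threshold (exact binomial, adjusted p = 0.352). The call was lost for the 1167 regions found in all 4 libraries (log2 ratio of -0.07, exact p = 0.484) and for regions from the upper 50% of each list (-0.19, exact p = 0.0601). The deficit was larger without replicate 3 (-0.33, exact p = 1.2e-07) and in the conservative list (-0.32, exact p = 3.0e-12). An expectation from TSS counts takes no account of the number of X copies in the embryos, so the deficit need not be a preference in binding. The small arm 4 held 6 regions, 4.23 per 100 TSS, where the other arms held between 9.86 on X and 12.1 on 3L.

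Genes of developmental signalling were bound most often. In all, 1768 of 13945 protein-coding genes (12.7%) had a shared region at a TSS. Of the 42 genes of the Wnt, Hedgehog, BMP and EGF receptor pathways, 27 were bound (64.3%; log2 odds ratio 3.63 ± 0.46 SE; Fisher's exact test, adjusted p = 1.7e-13), and 63.1% ± 9.22 (SD, n = 4) had a peak in the library lists, more than among all genes in 4 of 4 libraries. They included spi, a ligand of the EGF receptor (rank percentile 98.1 ± 0.689, SD, n = 4; 2L, 19575157 to 19575735), brk, a repressor of Dpp targets (97.2 ± 1.22; X, 7307501 to 7308054), sty, an antagonist of receptor tyrosine kinase signalling (91.6 ± 4.44; 3L, 3418303 to 3418934), and the Wnt ligand wg (76.6 ± 2.58; 2L, 7306785 to 7307214). The members arm and ci had no shared region. Random genes matched on length and number of TSS were bound in 24.3%, and the list stayed above them with an adjusted p of 0.0046 in the permutation test.

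Another 7 lists passed the threshold with more bound genes than the rest of the genome, each of them above all genes in 4 of 4 libraries, and chinmo itself is a member of 3. In the JAK/STAT pathway 8 of 15 genes were bound (log2 odds ratio 2.97 ± 0.72 SE, exact test, adjusted p = 0.00085), among them chinmo, the feedback inhibitor gene Socs36E (96.3 ± 1.15, SD, n = 4), the transcription factor gene Stat92E (89.9 ± 5.19) and Socs16D (84.6 ± 6.15), but not et or Socs44A. Among BTB zinc finger genes 9 of 17 were bound (2.95 ± 0.68 SE, exact test, adjusted p = 0.00059), with chinmo, BtbVII (97.3 ± 0.95), Trl, which encodes the GAGA factor (85.4 ± 3.32, n = 3), and lola (84.8 ± 3.38) highest and with no region at ab and bab1. Among axon guidance genes 13 of 34 were bound (2.12 ± 0.50 SE, exact test, adjusted p = 0.00084), with the semaphorin gene Sema1b (99.1 ± 0.975), the cell adhesion gene Nrg (94.98 ± 4.57), the Slit receptor gene robo2 (91.4 ± 4.68) and trn (90.3 ± 3.08); beat-Ia and comm had none. Temporal identity genes were bound in 9 of 27 cases (1.83 ± 0.58 SE, exact test, adjusted p = 0.015), with chinmo, hth (93.5 ± 5.68), nub (90.4 ± 5.57) and grh (81.9 ± 4.97), and without B-H1 and B-H2. Against random genes matched on length and number of TSS, none of these 4 lists passed the threshold (bound in 21.2%, 33.1%, 24.6% and 25.7%, adjusted permutation p of 0.0705, 0.379, 0.340 and 0.701 in the order given). The call for temporal identity was also lost without replicate 4 (log2 odds ratio 1.46, exact test, adjusted p = 0.0655), in the conservative list (1.43, 0.0546) and with a TSS window of 5000 bp (1.12, 0.197), and it was kept in regions found in all 4 libraries and in those from the upper 50% of each list. The call for axon guidance was lost with that window (log2 odds ratio 0.97, exact test, adjusted p = 0.197) and in regions from the upper 50% of each list (1.59, exact test, adjusted p = 0.0762).

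The Notch pathway and the Polycomb and trithorax genes each had 8 of 28 genes bound (log2 odds ratio 1.52 ± 0.59 SE, exact test, adjusted p = 0.0453), and segmentation genes 9 of 32 (1.48 ± 0.56 SE, exact test, adjusted p = 0.0438). Bound Notch members were led by the coactivator gene mam (93.2 ± 6.18, SD, n = 4), E(spl)m3-HLH (91.7 ± 3.92), numb (81.1 ± 4.29) and E(spl)mbeta-HLH (78.3 ± 7.34), while aph-1 and Brd were not bound. Bound chromatin genes were led by jing (98.4 ± 1.34), Su(z)2 (97.2 ± 1.04), Trl and Psc (84.9 ± 8.53), without ash1 and ash2. Bound segmentation genes were led by hry (86.2 ± 13.3), cnc (85.7 ± 9.87), wg and odd (72.7 ± 12.8), without bcd and btd. These 3 calls lay close to the threshold. Leaving out a replicate also lowered the requirement from 3 of 4 to 2 of 3 libraries. Notch lost its call without each replicate in turn (exact test, adjusted p from 0.103 to 0.196, log2 odds ratio down to 1.00 without replicate 3), the chromatin list without replicate 1, 3 or 4 (0.0849 to 0.125, log2 odds ratio 1.15 to 1.24) and segmentation without replicate 1 or 2 (0.0586 and 0.0862, log2 odds ratio 1.32 and 1.25). Notch and the chromatin list also lost theirs when regions in 2 of the 4 libraries were enough (log2 odds ratio 0.84 and 1.07, exact test, adjusted p = 0.275 and 0.166). In the smaller set from the upper 50% of each list all 3 missed the threshold with log2 odds ratios that were no lower, 1.63, 1.63 and 1.70 (exact test, adjusted p from 0.0651 to 0.0916). With a TSS window of 5000 bp they were 1.24, 1.03 and 0.33 (0.107 to 0.760). Matched genes were bound in 13.4%, 21.7% and 17.6%, with an adjusted permutation p of 0.179, 0.701 and 0.454, so that for Notch the matched share was near that of all genes.

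A pair of families was bound less often than the rest, with 5 of 117 cuticle protein genes (4.27%; log2 odds ratio -1.58 ± 0.63 SE, exact test, adjusted p = 0.0122) and 1 of 119 odorant and taste receptor genes bound (0.84%; -3.53 ± 1.19 SE, exact test, adjusted p = 3.1e-05). The bound receptor gene was Or88a (96.2 ± 1.27, SD, n = 4; 3R, 14108504 to 14108748), while Gr10a and Gr10b had none. Bound cuticle genes were led by Cpr73D (84.1 ± 8.75), Cpr67Fb, Cpr65Aw and TwdlN, and Ccp84Aa and Ccp84Ab were not bound. Both were below all genes in 4 of 4 libraries. Receptors stayed below matched genes (permutation, adjusted p = 0.0138) and cuticle genes did not pass against them (permutation, adjusted p = 0.616). The cuticle call was also lost in regions from the upper 50% of each list (log2 odds ratio -1.82, exact test, adjusted p = 0.0651) and with a TSS window of 5000 bp (-0.45, exact test, adjusted p = 0.269).

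The other 13 lists did not pass. Hox genes were bound in 3 of 8 cases (Ubx and abd-A highest; exact test, adjusted p = 0.115), ecdysone genes in 8 of 32 (EcR at 98.9 ± 0.555 and ftz-f1 at 94.2 ± 4.36, SD, n = 4; exact, 0.106), glial genes in 5 of 18 (Gli, loco; exact, 0.115) and midgut, fat body and tracheal genes in 7 of 25 (rib, srp; exact, 0.0662). The ecdysone and glial lists passed without replicate 3 (exact test, adjusted p = 0.0382 and 0.0163) and without replicate 4 (0.0299 and 0.0108), and the midgut list without replicate 1 (0.0312). All 3 also passed with all 4 libraries when regions in 2 of them were enough (exact test, adjusted p = 0.0265, 0.0093 and 0.0349). With the nearest TSS alone all 3 passed as well (exact test, adjusted p = 0.0232, 0.0422 and 0.0216). Both alternatives were chosen after the data were seen. With the planned gene body and 1000 bp around it, of the 3 only the ecdysone list passed (log2 odds ratio 1.80, exact test, adjusted p = 0.0057). None of the 3 passed against random genes matched on length and number of TSS, which were bound in 23.9%, 23.7% and 21.2%. Ribosomal protein genes were bound in 14 of 92 cases (15.2%, with RpL32 and RpS2 highest, exact test, adjusted p = 0.569). They were taken as a mostly strongly transcribed list, but transcription was not measured here and the list also holds genes named as -like. Counts were 6 of 34 for neuroblast and proneural genes (numb, SoxN), 6 of 40 for muscle (Msp300, Zasp52), 5 of 37 for the cell cycle (trbl, CycB), 4 of 40 for neuronal function (ple, slo), 4 of 21 for heat shock (Hsp68, Hsc70-4), 3 of 16 for sex determination and gonad (esg, foxo), 2 of 18 for hemocytes (Pvr, srp) and 1 of 18 for the germline (tud), with adjusted p from 0.506 to 1 in the exact test. In the longest list of the series, an alternative chosen after the data were seen, those for muscle (log2 odds ratio 1.20, exact test, adjusted p = 0.0261), the cell cycle (1.36, 0.0213) and sex determination and gonad (3.70, 0.00036) passed.

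**Figure D4:**
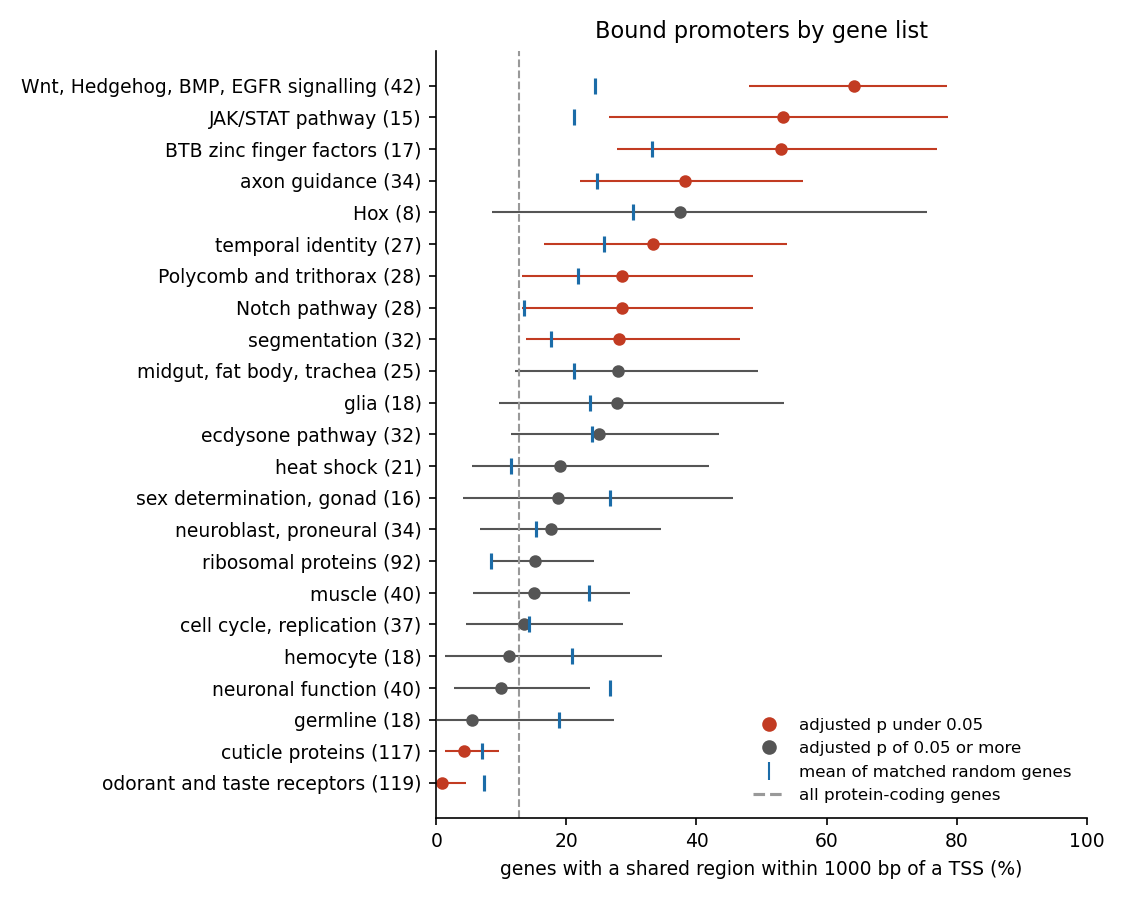
Percentage of the genes of each list with a shared region within 1000 bp of a TSS (x axis), with the number of genes in parentheses and exact binomial 95% intervals as whiskers; red points passed the threshold against all other genes. Blue ticks mark the mean of random genes matched on length and number of TSS, and the dashed line all protein-coding genes (12.7%); the signalling list at 64.3% and the receptor list at 0.84% are the 2 that also passed against matched genes.

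Small non-coding genes were not bound more often than protein-coding ones. A shared region lay within 1000 bp of the start of 39 of 290 tRNA genes (13.4%, exact test, adjusted p = 0.657), 19 of 301 snRNA and snoRNA genes (6.31%, log2 odds ratio -1.07 ± 0.34 SE, exact test, adjusted p = 0.0017) and 19 of 260 miRNA genes (7.31%, -0.85 ± 0.34 SE, exact test, adjusted p = 0.012). Protein-coding genes were scored at any annotated TSS and these genes at their start alone, so part of a deficit can come from the rule. Neighbouring genes near the same region count separately in the exact test, so its p-values here may be too small. The tRNA result turned with the number of libraries required and with the libraries kept. In regions found in all 4 libraries tRNA genes were bound less often (log2 odds ratio -1.42, exact test, adjusted p = 0.0019). They were bound more often in the conservative list (1.32, exact test, adjusted p = 6.3e-13), in regions found in at least 2 of the 4 (0.72, exact test, adjusted p = 0.00053), an alternative chosen after the data were seen, and in regions found in 2 of the other 3 without replicate 3 (0.88, exact test, adjusted p = 4.2e-05) or without replicate 4 (0.80, exact test, adjusted p = 0.00052), but did not pass under the same rule without replicate 1 or 2. The log2 odds ratio of snRNA and snoRNA genes was -0.59 without replicate 3. The call for miRNA genes was lost in regions found in all 4 libraries (-0.45, exact test, adjusted p = 0.233) and in regions from the upper 50% of each list (-0.37, exact test, adjusted p = 0.390).

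CGATA and GAGAG sequences were more frequent at the centres of bound regions than beside them, and 46.1% of the 2150 shared regions held neither at the centre. CGATA, the core of the site of the insulator protein BEAF-32, occurred within 50 bp of the centre in 31.6% of the shared regions and in 10.05% of the flanks (log2 ratio of discordant regions 2.09 ± 0.13 SE, McNemar's exact test, adjusted p = 9.8e-68). Its longer palindrome TATCGATA, the site of the DREF factor, occurred in 8.47% against 0.605% (3.86 ± 0.42 SE). GAGAG, the site of the GAGA factor, occurred in 26.0% against 12.7% (1.29 ± 0.12 SE, exact test, adjusted p = 8.8e-28), and the CACACA repeat in 19.3% against 10.4% (1.02 ± 0.13 SE). GGTCACA, CACGTG and CAGCTG were also more frequent at centres, with log2 ratios of 1.43, 1.05 and 0.77. All 7 were above the flank in 4 of 4 library lists; without replicate 2 the call for CACGTG was lost (0.78, exact test, adjusted p = 0.0532). Without replicate 3 the log2 ratio was 0.62 for CACGTG and 2.25 for GGTCACA, and in regions from the upper 50% of each list the call for GGTCACA was lost (1.12, exact test, adjusted p = 0.116). In the library lists CGATA occurred at 24.6%, 24.4%, 34.2% and 32.8% of summits in replicates 1 to 4, and GAGAG at 26.1%, 26.6%, 23.7% and 24.1%.

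CGATA was a sequence of promoter-proximal regions. Among promoter-proximal regions, CGATA occurred in 41.0% of centres and 10.2% of flanks; among the 653 distal regions it occurred in 10.1% and 12.3% (log2 ratio -0.32 ± 0.26 SE, McNemar's exact test, adjusted p = 0.405). In a test chosen after the data were seen, regions with CGATA were promoter-proximal in 90.3% of cases and regions without it in 60.1% (log2 odds ratio 2.62 ± 0.20 SE, Fisher's exact test, adjusted p = 1.1e-50). GAGAG was above the flanks in both groups, at 24.8% against 14.2% near promoters and 28.6% against 11.8% in distal regions. CACACA occurred in 26.5% of distal centres against 9.65% of their flanks. The E-box CACGTG passed in distal regions (3.37% against 0.613%, exact test, adjusted p = 0.0014) and not in promoter-proximal ones (1.80% against 1.07%, exact test, adjusted p = 0.160); the difference between the groups was not tested for CACACA and CACGTG. For GAGAG it did not pass, with 66.5% of the regions with GAGAG and 70.7% of those without it promoter-proximal (log2 odds ratio -0.28 ± 0.15 SE, Fisher's exact test, adjusted p = 0.0692).

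**Figure D5:**
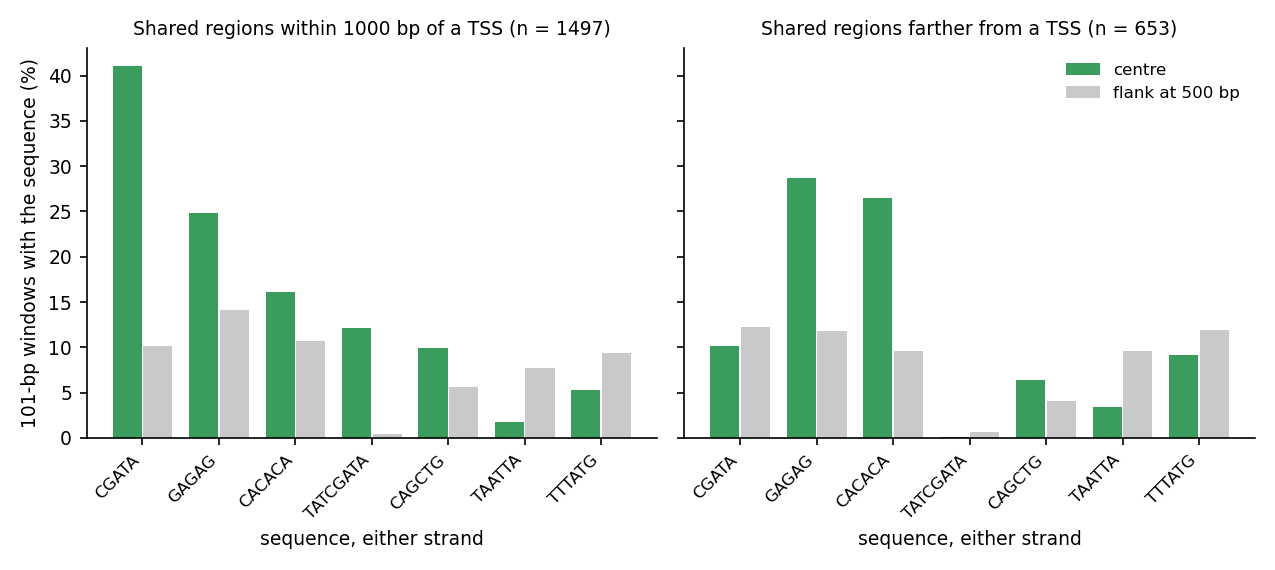
Percentage of windows of 50 bp to each side with each sequence on either strand (y axis) at the centres of shared regions (green) and in flanks 500 bp away (grey), for promoter-proximal (left) and distal regions (right). CGATA reaches 41.0% at promoter-proximal centres and 10.1% at distal ones, while GAGAG reaches 24.8% and 28.6%.

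Several AT-rich sequences were rarer at centres than in flanks. The homeodomain site TAATTA occurred in 2.23% against 7.35%, TTTATG in 6.51% against 10.2%, the STAT site TTCNNNGAA in 1.44% against 3.49%, CTTTGAT in 0.465% against 1.58% and ACAATG in 3.95% against 6.05%, each below the flank in 4 of 4 libraries; without replicate 2 the call for CTTTGAT was lost (log2 ratio -0.73, from -1.82, exact test, adjusted p = 0.0856), and without replicate 1 or 4 its log2 ratio was -1.11 or -0.91. It was also lost in regions from the upper 50% of each list (-0.71, exact test, adjusted p = 0.362). ACAATG lost its call there (-0.64, exact test, adjusted p = 0.0587) and with flanks at 300 bp (-0.44, exact test, adjusted p = 0.0585), and without replicate 3 its log2 ratio was -0.36, from -0.63. The centres held 48.4% GC and the flanks 40.3%. With flanking windows of equal GC content, chosen as an alternative after the data were seen, TAATTA, TTCNNNGAA and TTTATG no longer passed (McNemar's exact test, adjusted p = 0.229, 0.302 and 0.302). The Tramtrack site AGGATAA occurred at 0 of 2150 centres, which allows a share of up to 0.14%, and in 1.02% of flanks (exact test, adjusted p = 1.6e-06); without replicate 2 the log2 ratio was -2.48. Sites of Zelda, Su(Hw), Pho, AP-1, Grainyhead and GATA factors and the E-box CAGGTG did not pass the threshold (exact test, adjusted p from 0.134 to 0.600). Of these, the Grainyhead site passed without replicate 3 and without replicate 4 (log2 ratio 1.41 and 1.76), the GATA site without replicate 1 and without replicate 3 (-0.85 and -0.80), the AP-1 site without replicate 3 (1.06) and CAGGTG without replicate 4 (-0.54). The Grainyhead site also passed in the conservative list (1.32, exact test, adjusted p = 6.2e-05) and with windows of 100 bp to each side (0.95, 0.0216). It passed in the longest list as well (1.41, exact test, adjusted p = 1.2e-09), but not against flanks of equal GC content. With whole peaks overlapped, the GATA and AP-1 sites passed (-1.22 and 1.02), and in the conservative list CAGGTG did (-0.41). Against flanks of equal GC content CAGGTG and the Zelda site passed as rarer (-1.15 and -1.31, exact test, adjusted p = 7.4e-07 and 0.0334). The Pho site passed as rarer in regions found in all 4 libraries (-0.70, exact test, adjusted p = 0.0431) and in regions from the upper 50% of each list (-1.12, exact test, adjusted p = 0.00076). Among all 2080 6-mers, 466 were more frequent and 483 less frequent at centres. The 6-mers were not tested against flanks of equal GC content, so part of these counts may go with GC content. The most enriched was TATCGA (21.7% against 3.26%, log2 ratio 3.15 ± 0.21 SE, McNemar's exact test, adjusted p = 1.9e-77), followed by CGATAG (18.9% against 2.51%) and ATCGAT (19.2% against 4.00%). Among the first 15, 8 held CGAT on either strand, and GAGCGA, AGAGCG and GAGAGC were also among them.

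The stronger parts of the library lists were more often promoter-proximal than the weaker parts, a difference that passed the threshold in 2 of 4 libraries. In the top 25% of each library's list by signal value 71.3% ± 4.08 of peaks were promoter-proximal and in the bottom 25% 63.6% ± 4.31 (SD, n = 4), a difference of 7.77 ± 3.12 percentage points. It was positive in 4 of 4 libraries and passed the threshold in replicates 2 and 4 (Fisher's exact test, adjusted p = 2.8e-07 and 7.3e-05), while replicates 1 and 3, at 4.55 and 5.77 points, both stood at an adjusted p of 0.0533. The top and bottom 10% differed by 5.83 ± 3.33 points (SD, n = 4), and only replicate 2 passed (Fisher's exact test, adjusted p = 0.0082). Of the 100 shared regions found in all 4 libraries with the highest mean rank, 56 were promoter-proximal, against 69.6% of all shared regions. The chinmo locus held 12 of these 100, and when it was left out the count was 65 of 100. These shares were not tested against each other, so the very strongest regions cannot be said to differ.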

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

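The tests on the longest list of the whole series were chosen only after the result was seen. Of 59 values measured in each of the 4 libraries, 5 were flagged because 1 library stood apart from the other 3. The rule compared the gap to the nearest library with the range of all 4. Chance would flag about 1 in 20, a rate that need not hold for small counts with ties. Where the other 3 libraries tie, the rule flags even a difference of 1 gene. None of the 5 was tested against counting error, so the flags do not show that a library differs. CACGTG occurred at 2.10% of summits in replicate 1, above the other libraries, which lay between 1.88% and 1.90%. AGGATAA occurred at 0.0658% in replicate 4, the lowest share. Of the muscle genes, 12.5% had a peak in replicate 3, below the rest. Of the cell cycle genes, 24.3% had a peak in replicate 2, 9 genes against 8 in each of the others. Of the odorant and taste receptor genes, 0.84% had a peak in replicate 3, 1 gene against 2 in each of the others.

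A signal also stood in data that the comparisons above do not use. The longest list of the whole series held 13848 peaks, and 8380 of them (60.5%) had no summit within 100 bp in the thresholded list of any single library. Of these, 43.6% were promoter-proximal. CGATA occurred at 16.1% of their summits and 11.8% of their flanks (log2 ratio 0.53 ± 0.07 SE, McNemar's exact test, adjusted p = 3.8e-15), and GAGAG at 17.2% and 10.8% (0.80 ± 0.07 SE, exact test, adjusted p = 9.0e-33). Of the 2150 shared regions, 98.7% had a summit in that list.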

How the results depend on the processing

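The list of the whole series with most peaks, regions in at least 2 of the 4 libraries, the set without the chinmo locus, local shifts, flanks of equal GC content and the nearest TSS alone were chosen after seeing the data; all other alternatives were planned. Of 113 recomputed values of the main results, 99 kept their direction and their side of the threshold, moved by less than the replicate spread, or, for a count, stayed within 1.5 times. The promoter-proximal share stayed between 51.9% and 77.5% and above its expectation in every alternative run. The number of shared regions was 1167 when all 4 libraries were required, 1102 from the upper 50% of each list, 5841 in the conservative list, 13848 in the longest one and 3491 in at least 2 of the 4 libraries, by construction of those sets, and ran from 2443 to 3196 without each replicate, where the rule was also loosened from 3 of 4 to 2 of 3 libraries. The deficit on X lost its call for regions found in all 4 libraries (log2 ratio -0.069) and in the upper 50% (-0.19), sets with fewer regions. The number of gene lists past the threshold fell from 10 to 5 with the upper 50%, to 4 with a TSS window of 5000 bp and to 2 against genes matched on length and number of TSS, and was 8 to 10 without each replicate; the classes of non-coding genes past it fell from 2 to 1 with the upper 50%, and rose to 3 without replicate 3, without replicate 4, in at least 2 of the 4 libraries, in the conservative list and in the longest list, each time through tRNA genes. In regions found in all 4 libraries tRNA genes turned to bound less often (-1.42); the cause was not tested. Motifs past the threshold were 13, from 11 to 16 without each replicate, and 4 in distal regions alone, which were 653 of 2150. There CGATA (-0.32), TATCGATA (-1.58) and GGTCACA (-0.65) stood below the flank, but none passed (McNemar's exact test, adjusted p = 0.405, 0.5 and 0.855). TATCGATA occurred in only 0.153% of distal centres against 0.613% of flanks, and GGTCACA in 0.459% against 0.766%. The cause of the lost excess was not tested. The mean overlap rose to 90.9% for the top 500 summits, and by unadjusted p the top and bottom 10% passed in 1 library, where the top and bottom 25% passed in 3 (2 by adjusted p). Of 845 values for single lists, motifs and classes, 740 stayed on their side of the threshold, among them values short of it that changed sign, 61 fell short of it in the same direction, 40 newly passed it and 4 turned. Read depth was unknown, so how far it sets the list lengths could not be tested.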

Other observations

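Tests for the chinmo locus, for GAGAG with CGATA, for GAGAG or CGATA in regions without the other sequence, for GAGAG at head-to-head pairs and for ribosomal protein genes were chosen only after the result was seen, as was the use of distal regions, chosen beforehand as a separate set, to weigh promoter position; the other tests in this part were written down before their result. GAGAG occurred in 11.8% of the 680 shared regions with CGATA and in 32.6% of the 1470 without it (log2 odds ratio -1.85 ± 0.19 SE, Fisher's exact test, adjusted p = 2.0e-26). The 11.8% lay near the 12.7% of flanks with GAGAG over all shared regions. The difference is thus an excess of GAGAG in regions without CGATA and does not show that these sequences avoid each other. Of the 2150 regions, 991 held neither. Of promoter-proximal regions with CGATA, 42.0% lay within 1000 bp of TSS of a head-to-head gene pair, against 14.9% of those without (log2 odds ratio 2.04 ± 0.18 SE, exact test, adjusted p = 8.1e-31). The 8 developmental lists joined here held 181 genes and were not the same set as the lists reported above with more bound genes. Their genes stood at 3.09% of promoter-proximal regions with CGATA and 8.04% of those without (-1.43 ± 0.38 SE, exact test, adjusted p = 7.9e-05). Both differences also passed among regions without GAGAG (1.87 and -1.39). For GAGAG the share at developmental genes was 9.14% against 4.98% over all promoter-proximal regions (0.95 ± 0.32 SE, exact test, adjusted p = 0.0062), where the group without GAGAG holds most regions with CGATA. Among regions without CGATA it was 9.93% against 7.06% and did not pass (0.54 ± 0.36 SE, exact test, adjusted p = 0.151), so a link of GAGAG with these genes stays open. Head-to-head pairs were rarer with GAGAG, over all promoter-proximal regions (-1.10 ± 0.22 SE, exact test, adjusted p = 4.9e-07) and among those without CGATA (-0.66 ± 0.31 SE, exact test, adjusted p = 0.0381). A hypothesis from these values is that bound promoters with CGATA may more often serve paired genes and less often developmental regulators.

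The 4 libraries formed 2 pairs by the order of their peak signals. Over the 1167 regions found in all 4, Spearman's rho across regions, which are not independent replicates, was 0.756 between replicates 1 and 2 and 0.740 between 3 and 4, and from 0.518 to 0.599 in the 4 other pairs. The labels give no batch, so the source of the split was not tested.

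For the sequences at the centres, the tables argue against base composition as the whole reason and against a property shared by all promoters. Against flanks of equal GC content the log2 ratio was 2.06 for CGATA, from 2.09. For GAGAG it was 0.72 ± 0.11 SE, from 1.29, so that part of the GAGAG excess went with GC content. At the same distance from the TSS of genes with no peak in any library, CGATA occurred in 17.4% of windows against 41.0% at bound promoters (log2 ratio 1.88 ± 0.14 SE, McNemar's exact test, adjusted p = 3.2e-48) and GAGAG in 10.2% against 24.8% (1.48 ± 0.15 SE), though bound windows also held more GC (48.0% against 41.1%). The unbound promoters were not matched on activity, so the comparison cannot separate binding from a property of active promoters, which stays open. In distal regions the log2 ratio was -0.32 ± 0.26 SE for CGATA, as it would be if its excess came with promoters alone, and 1.54 ± 0.22 SE for GAGAG, which argues against that for GAGAG. CGATA may go with a stronger signal, as its share was higher in the top than in the bottom 25% of the list in 4 of 4 libraries, by 11.9 ± 4.80 percentage points (SD, n = 4; 7.46, 8.79, 13.3 and 18.1 in replicates 1 to 4), while for GAGAG the difference of 3.41 ± 4.67 points passed in replicates 1 and 2 (5.01 and 9.16) and not in 3 and 4 (-1.44 and 0.922), the same pairs as in the order of the signals, which leaves its part open. Open chromatin and other proteins at these sites were not tested, nor was any biological explanation, since the design has 1 group.

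For the dense cluster at chinmo, a fault of 1 library was argued against by the peak counts of each library. The 130 kb window held 39, 38, 32 and 31 thresholded peaks in replicates 1 to 4, each time more than any other such window. Its 3 strongest regions ranked within the first 10 peaks in 4 of the 4 libraries, though they were chosen after their ranks were seen. Extra copies of the locus in the tagged flies remain open: the labels call the flies transgenic, and a locus present in more copies could give more fragments. When the signal values of the locus were halved, as for a doubled copy number, at least 2 of its peaks stayed in the top 1% of the list in every library, in place of 9 to 12, but the copy number is not known and the bound rests on that assumption. Binding of the factor to its own gene and added copies therefore cannot be told apart here, as no control library was analysed.

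For the signalling genes, gene length and the number of annotated TSS were argued against as the whole reason, as 0 of 10000 draws of matched genes held as many bound genes as the 27 of the list. Strong transcription stays open: ribosomal protein genes were bound less often (15.2% against 64.3%), but they are matched by genes that are bound in 8.41%, against 24.3% for the signalling list. Over its own matched genes the signalling list stood at a log2 excess of 1.36 and ribosomal protein genes at 0.82, a difference of 0.54 ± 0.48 (counting SE) that is within 2 SE. Whether the promoters of these genes are more accessible in embryos was not tested, and no biological explanation was tested.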
